A study of Mus musculus with 4 samples.

How the data were processed

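Total RNA of mouse E14 embryonic stem cells was measured on 4 one-colour Affymetrix arrays with biotin-labelled targets, 2 from untreated cells and 2 from cells given 0.5 mM valproic acid (VPA) for 4 h. The cells grew on mitotically inactivated embryonic fibroblasts with serum and leukemia inhibitory factor, per the labels' protocols. Each array was assigned to its group by the treatment named in its label. The labels call the samples replicates, and nothing in them says that they came from separate cultures. The p-values of single probe sets therefore measure only the spread between these arrays, which may be technical.

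The values deposited by the authors are log2 signals, 1 per probe set and array, made with RMA in Affymetrix Expression Console 1.1 per the submitters' processing notes. RMA corrects background, quantile-normalizes across arrays and summarises the probes of a probe set. Which arrays were normalized together is not given in the sources used here. The log2 scale was taken from that method and from the values, which ran from 1.41 to 13.95 with array medians between 3.80 and 3.82. The sorted values of the arrays were close but not identical, with a largest distance of 0.080 from the mean of a rank, so a second quantile normalization was among the alternatives. All 4 arrays held 35556 probe sets, and no scanner files, detection calls or sequences were used here. For arrays the number of replicates limits the precision.

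Gene names came from the platform annotation paired with the probe sets. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none here. Gene identifiers of 21698 single-symbol probe sets matched the RefSeq table of GRCm38.p6, and the match changed 0 symbols. That table was used only for names and gene lengths, because no build is given for the array, and no coordinates are reported. A gene with several probe sets was represented by the one with the highest mean over all arrays, which gave 19938 genes. Probe sets with several symbols were tested but not named.

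The deposited log2 values were tested as they stand. The 2 groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without trend or robust options, over all probe sets and with treatment as the only term. The tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all probe sets, and the threshold was an adjusted p of 0.05. The fit has 2 residual degrees of freedom, to which the moderation added 2.93. As a description without a test, probe sets were counted whose group means lay at least 1.5-fold apart with no overlap between the groups. An exact permutation test of 2 arrays against 2 cannot give a p below 0.33.

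Gene lists, 30 in number, were written from textbook knowledge before the data were examined. They cover pluripotency and differentiation markers, chromatin factors, genes reported to respond to inhibitors of histone deacetylases, cell cycle, stress and metabolic genes, and markers of feeder, trophoblast, endoderm and blood cells. Of 872 names in the lists, 799 matched a represented gene. The lists were tested with limma's camera, which asks whether the genes of a list differ more, on balance, than the other genes, with a preset inter-gene correlation of 0.01 and adjustment over the 30 lists. With the preset correlation its p-values rest mainly on the spread of the statistics over genes. A small p there is no measure of how far a list's difference would recur in other cultures. The estimated correlation and fry were the alternatives. Values described as adjusted over the list alone are Benjamini-Hochberg values of the members' limma p within 1 list.

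The genes named in the report follow a rule fixed before the data were examined. It took the 12 genes per direction with the largest change among those passing the threshold, filled up with the genes of smallest unadjusted p at an absolute log2 difference of at least 0.5. It also took the 4 members of smallest p of each list that passed and of 6 lists that were always to be described, and 25 genes named in advance, of which 21 had a probe set with a single symbol. The other 4 (H1f0, Cdkn1a, T and Gapdh) were not analysed here. Predicted genes, olfactory and vomeronasal receptors, antigen receptor segments and small RNAs were counted but not named.

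The scripts were tested on simulated data with the spread of these arrays, in 20 sets of 35556 probe sets with 200 changed in each. Each simulated probe set was drawn independently of the others. For this comparison of 2 against 2, limma called 0.1% of 1.5-fold changes, 2.5% of 2-fold changes, 83.7% of 4-fold changes and 95% of 8-fold changes. With no effect, a mean of 1799.2 probe sets had an unadjusted p under 0.05 and a mean of 0.05 lists passed camera. A list of 32 genes moved by −0.2 on the log2 scale, among 19938 genes, passed camera with the preset correlation in 20 of 20 sets, with an estimated correlation in 0 and with fry in 2. With no effect a mean of 0.9 lists passed fry's mixed test. Because simulated genes did not vary together, these list results do not show how often lists of correlated genes pass by error. In the data the estimated correlation was 0.246 for heat shock and oxidative stress and 0.118 for primed epiblast genes. It was 0.028 for core pluripotency and −0.078 for 2-cell-like genes.

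The alternatives were centring each array on its median, a second quantile normalization, leaving out the dimmer probe sets, other variance models, a minimum fold, 1 probe set per gene, the mean of a gene's probe sets, a replicate block, other thresholds and leaving out each array. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.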

Results

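The data are 4 arrays of mouse E14 embryonic stem cells, a line kept on fibroblast feeders. Untreated cells and cells exposed to 0.5 mM VPA for 4 h each gave 2 arrays. VPA is a short branched fatty acid that inhibits histone deacetylases, and the series asks how a low dose given for a short time alters gene expression. Each array reported 35556 probe sets as log2 signals. The SD over probe sets of the difference between replicates was 0.311 in untreated and 0.285 in VPA cells. Across probe sets, which are not independent replicates, Pearson's r was 0.991 between the untreated arrays and 0.993 between the VPA arrays. It lay between 0.988 and 0.992 across the groups, and untreated replicate 2 was the array least like the others. Untreated replicate 1 was closer to both VPA arrays than to untreated replicate 2. The SD of its difference was 0.297 from VPA replicate 1 and 0.301 from VPA replicate 2, against 0.311 from untreated replicate 2.

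After 4 h with VPA, the genes of smallest p among those above their untreated level included Armcx3 (a mitochondrial outer membrane protein), Lipa (lysosomal acid lipase) and Zbtb18 (a transcriptional repressor). Among those below it they included Setd1b (a histone methyltransferase), Mycn (a growth-promoting transcription factor) and Prdm14 (a regulator of naive pluripotency). The largest of these differences was about 2.54-fold and most were under 2-fold. As a group, core pluripotency genes were lower with VPA by a mean of 0.19 on the log2 scale (adjusted p = 9.4e-06 in camera, and adjusted p = 0.506 with an estimated correlation). No single gene passed the test across all probe sets.

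With limma and Benjamini-Hochberg adjustment, 0 of 35556 probe sets were called, and the smallest adjusted p was 0.462. At an unadjusted p under 0.05 there were 3269 probe sets, of which 2049 were higher and 1220 lower with VPA, where 5% of all probe sets is 1778. After a second quantile normalization those counts were 1670 higher and 1542 lower. Group means lay at least 1.5-fold apart without overlap for 990 probe sets, 717 higher and 273 lower, and for 589 and 363 after the second normalization. On the deposited values, the splits of the arrays that mix treated and untreated ones gave 562 and 644 such probe sets. A treatment difference widens the spread within the groups of those splits, so they do not measure what chance alone gives. In 40.4% of probe sets the untreated and VPA groups did not overlap at any fold, and chance gives 33.3%. Many of the 1.5-fold differences came from probe sets without a gene name: 479 higher and 176 lower belonged to 6617 unnamed probe sets with low identifiers, against 208 higher and 67 lower among 23410 named ones.

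The 12 genes named for the upward direction did not pass the adjusted test, and their log2 differences lay between 0.81 and 1.35. Armcx3 (probe set 10568363) went from 5.57 ± 0.33 to 6.91 ± 0.048 (SD, n = 2), a difference of 1.35 ± 0.18 (SE), and its other probe sets gave 1.23 and 1.15. Lipa (10467139) went from 5.41 ± 0.084 to 6.39 ± 0.016, a difference of 0.97 ± 0.11. Rtkn2 differed by 0.93 ± 0.12, the zinc finger gene Zfp667 by 0.92 ± 0.13 and Fn3krp, a kinase of glycated proteins, by 0.92 ± 0.12. The transcriptional coregulator Sertad3 was 0.89 ± 0.11 higher and Nxpe3 0.87 ± 0.10. Nemp1, a nuclear envelope protein, and the phosphatase gene Phospho2 were both 0.85 higher, as was the lysophospholipid acyltransferase gene Mboat2. Pfkfb2, an enzyme that controls glycolytic flux, differed by 0.84 ± 0.12 and Zbtb18 by 0.81 ± 0.11. Their unadjusted p ran from 0.00033 to 0.00086 with limma, and the adjusted p was 0.462 for each.

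The 12 genes named for the downward direction also did not pass, with log2 differences between −0.59 and −0.95. C2cd4a went from 5.88 ± 0.19 to 4.94 ± 0.0060 (SD, n = 2), a difference of −0.95 ± 0.13 (SE). Setd1b (probe set 10525495) went from 6.49 ± 0.087 to 5.62 ± 0.10, a difference of −0.88 ± 0.12, and its other probe set gave −0.97. Brpf3, a scaffold of histone acetyltransferase complexes, differed by −0.70 ± 0.11 and Asxl1, a partner of a histone deubiquitinase, by −0.69 ± 0.12. Prdm14 differed by −0.86 ± 0.15 and Mycn by −0.68 ± 0.10, the latter from 8.82 to 8.14. The growth factor gene Pdgfa differed by −0.67 ± 0.11, the homeobox gene Msx1 by −0.67 ± 0.12 and Inhbb, an activin subunit, by −0.59 ± 0.10. Dusp27 (−0.65 ± 0.11), the class I histocompatibility gene H2-Q5 (−0.64 ± 0.11) and Nexmif (−0.59 ± 0.11) completed the set. The adjusted p was 0.462 for each.

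**Figure D1:**
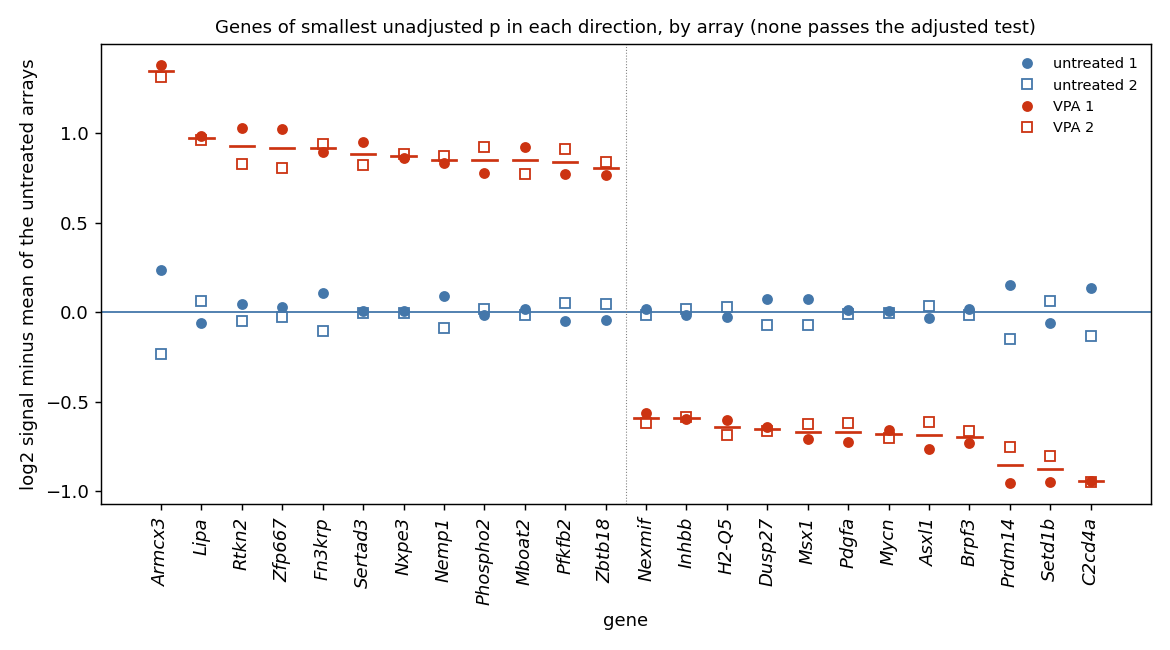
Log2 signal of 24 genes, the 12 of smallest unadjusted p in each direction at an absolute log2 difference of at least 0.5, on each of the 4 arrays, relative to the mean of the untreated arrays (horizontal line at 0); circles are replicate 1, squares replicate 2, and red bars the mean of the VPA arrays. Both VPA arrays lie beyond both untreated arrays for every gene shown, from −0.95 for C2cd4a to 1.35 for Armcx3, and none of them passes the adjusted test. The choice by smallest p makes such a separation likely, so it is no further evidence of a difference.

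Core pluripotency genes were lower with VPA as a list of 32 genes, with a mean log2 difference of −0.19 and an adjusted p of 9.4e-06 in camera with the preset correlation. With an estimated correlation the adjusted p was 0.506. Of the members, 25 had a lower mean and 7 a higher one, and 7 were lower and 0 higher at an unadjusted p under 0.05. None was called over all probe sets, and 0 when adjusted over the list alone (smallest 0.077). Besides Prdm14, the members of smallest p were Gdf3, a ligand of the TGF-beta family, at −0.55 ± 0.11 (SE), the nuclear receptor gene Nr5a2 at −0.54 ± 0.12 and Sall4 at −0.43 ± 0.11. Nanog differed by −0.48 ± 0.14, from 10.77 ± 0.16 to 10.29 ± 0.15 (SD, n = 2). The remaining central factors differed by less: Pou5f1 (encoding Oct4) by −0.11 ± 0.14, Zfp42 (Rex1) by −0.27 ± 0.14, Esrrb by −0.20 ± 0.12, Klf4 by −0.089 ± 0.11 and Sox2 by 0.20 ± 0.19. The list's mean stayed below 0 with each array left out in turn, between −0.14 and −0.24, and its adjusted p stayed at or below 0.016. Fibroblast feeder markers, which would show RNA of the other cells in the culture, were also lower, by a mean of −0.059 over 38 genes (adjusted p = 0.049, and adjusted p = 0.606 with an estimated correlation). Their values were Ccdc80 −0.31 ± 0.11, Thy1 0.31 ± 0.12, Sparc −0.26 ± 0.11, Prrx1 −0.27 ± 0.14 and Col1a1 −0.28 ± 0.19. The feeder list lost its call without untreated replicate 2, where its mean was −0.016 (adjusted p = 0.491), and without VPA replicate 1 (0.130) or VPA replicate 2 (0.060), and its mean was −0.10 without untreated replicate 1.

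Primed epiblast genes and the measured part of the 2-cell-like genes were lower as lists too. Of the 24 names in the 2-cell-like list only 13 matched a represented gene. Zscan4a, Zscan4c, Zscan4d, Zscan4f, Tcstv1 and Dux were among those not analysed here. Primed epiblast genes had a mean of −0.15 over 19 genes (adjusted p = 0.0067 in camera), with 14 lower and 5 higher, and 2-cell-like genes had a mean of −0.16 over 13 genes (adjusted p = 0.0075), with 12 lower and 1 higher. With an estimated correlation the adjusted p was 0.506 for both. Adjusted over the list alone, 3 primed epiblast genes were called: Foxd3, a transcriptional repressor, was lower by −0.80 ± 0.16 (SE), Fgf5 by −0.61 ± 0.13, and Cldn6, a tight junction protein, was higher by 0.72 ± 0.13. Etv4 differed by −0.40 ± 0.11. Among 2-cell-like genes, Pramel7 differed by −0.43 ± 0.13, Usp17lc by −0.47 ± 0.19, Tdpoz3 by −0.24 ± 0.12 and Zfp809, a repressor of proviruses, by −0.22 ± 0.10, and 0 were called when adjusted over the list alone. Without VPA replicate 1 both lists missed the threshold (adjusted p = 0.062 for each).

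Developmental regulators listed as bound by Polycomb proteins were lower as lists. The list of such regulators outside the Hox clusters had a mean of −0.12 over 53 genes (adjusted p = 0.00023 in camera), with 44 lower and 9 higher, and Hox genes had a mean of −0.074 over 37 genes (adjusted p = 0.033), with 23 lower and 14 higher. With an estimated correlation the adjusted p was 0.506 and 0.597. No member of either was called when adjusted over the list alone. Besides Msx1, the regulators of smallest p were Lhx5 (−0.51 ± 0.12, SE), Pax8 (−0.44 ± 0.10) and Gbx2 (−0.35 ± 0.12). Among Hox genes they were Hoxb2 (−0.36 ± 0.12), Hoxb4 (0.29 ± 0.11), Hoxb6 (−0.29 ± 0.12) and Hoxd12 (−0.28 ± 0.12), all of low signal, between the 29.4th and 45.5th percentile of probe sets. Of the other regulators, Gbx2 lay at percentile 73.0, Pax8 at 62.3 and Lhx5 at 41.4. Whether the members were silent in these cells was not tested, nor was a signal-dependent trend for these lists. Hoxb1 lay at 4.83 in both groups, with a difference of 0.0026 ± 0.11 whose sign turned with either scaling alternative. The Hox list lost its call after a second quantile normalization (adjusted p = 0.132), with the dimmer probe sets left out (0.337) and without untreated replicate 2 (mean −0.031, adjusted p = 0.332), VPA replicate 1 (0.065) or VPA replicate 2 (0.069). Without untreated replicate 1 its mean was −0.12, and without VPA replicate 2 that of the other regulators was −0.077.

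Lineage markers did not shift as lists. Neural and neuronal genes had a mean of −0.016 over 40 genes (adjusted p = 0.33 in camera), and 0 were called when adjusted over the list alone. Syt11, a synaptotagmin, differed by 0.74 ± 0.14 (SE), Rab3a by 0.34 ± 0.12, Crmp1 by −0.48 ± 0.14, Pax6 by −0.37 ± 0.11 and the neuronal tubulin Tubb3 by −0.34 ± 0.13. Mean differences were −0.062 for 31 mesoderm and primitive streak genes (adjusted p = 0.057), −0.052 for 28 endoderm genes (0.138), −0.035 for 23 trophoblast genes (0.277) and −0.0030 for 16 blood and endothelial genes (0.693). The trophoblast median was above 0, at 0.019, and the trophoblast mean was −0.076 without untreated replicate 1 and 0.0062 without untreated replicate 2. The blood and endothelial mean was 0.015 without untreated replicate 2 and ran from −0.039 (without VPA replicate 1) to 0.033 (without VPA replicate 2). Without VPA replicate 2 the neural and mesoderm means were −0.024 and −0.038, and without VPA replicate 1 the neural mean was smaller in size than over all arrays. Gata6, an endoderm regulator, differed by −0.42 ± 0.11 at a low signal of 3.70 in untreated cells. Germline and methylation-silenced genes had a mean of 0.063 (adjusted p = 0.609) and imprinted genes 0.0084 with a median of −0.0017 and a test direction downward (0.829). The first of these was 0.14 without untreated replicate 1 and −0.017 without untreated replicate 2, and the second 0.035 and −0.018.

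VPA acts on enzymes that remove acetyl groups from histones. Histone acetyltransferases and acetyl-lysine readers were lower as a list, with a mean of −0.13 over 26 genes (adjusted p = 0.0034 in camera, and adjusted p = 0.506 with an estimated correlation). Of these, 18 were lower and 8 higher, and adjusted over the list alone 1 was called, Brpf3. Crebbp differed by −0.53 ± 0.14 (SE), Kat5 by −0.44 ± 0.12 and Brd2 by −0.31 ± 0.11. Polycomb and DNA methylation machinery genes had a mean of −0.067 over 34 genes (adjusted p = 0.026, and adjusted p = 0.506 with an estimated correlation), with Rybp at −0.50 ± 0.12, Ring1 at −0.47 ± 0.11, Jarid2 at −0.30 ± 0.11 and Yaf2 at 0.50 ± 0.17. Adjusted over the list alone, 0 of these were called. Both lists missed the threshold without VPA replicate 1 (adjusted p = 0.062 and 0.093), and the Polycomb machinery list also without untreated replicate 1 (adjusted p = 0.101). Histone deacetylases and their partners did not shift as a list, with a mean of 0.026 over 35 genes (adjusted p = 0.737) that was −0.018 after a second quantile normalization. Their members went both ways: Rcor2 by −0.54 ± 0.11, Gatad2b by −0.38 ± 0.10, Sin3a by 0.39 ± 0.12 and Hdac3 by 0.30 ± 0.11. Hdac1 differed by 0.14 ± 0.11, Hdac2 by 0.19 ± 0.15, Hdac8 by 0.11 ± 0.10 and Hdac11 by 0.19 ± 0.19. Linker and replication-independent histones had a mean of 0.071 over 14 genes (adjusted p = 0.443), which ran from 0.031 to 0.11 without VPA replicate 2 and VPA replicate 1.

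Genes reported elsewhere to respond to deacetylase inhibitors did not shift as a list, with a mean of 0.061 over 42 genes, 24 higher and 18 lower (adjusted p = 0.496 in camera). The list held 46 names, and H1f0, Cdkn1a, Hspa1b and H2bc12 were not analysed here, so the result does not cover them. The mean was 0.10 without untreated replicate 1 and 0.021 without untreated replicate 2. The list was among the 8 called by fry's mixed test, which takes differences in both directions (adjusted p = 0.039). That test does not compare a list with the other genes, so a list can pass where many genes differ. With no effect anywhere and genes drawn independently, a mean of 0.9 lists passed it in the simulation. At an unadjusted p under 0.05, 6 members were higher and 2 lower, and 0 were called when adjusted over the list alone. At that unadjusted p, 5.43% of the 23410 named probe sets were higher and 2.86% lower. After Syt11, the members of smallest p were Gla, a lysosomal galactosidase, at 0.46 ± 0.13 (SE), Crip2 at 0.43 ± 0.12 and Cited2 at −0.41 ± 0.12. Txnip differed by 0.14 ± 0.15, and Clu (0.056 ± 0.15) and Gsn (0.068 ± 0.12) had differences whose sign turned after a second quantile normalization. The cytoskeletal gene Actb lay at 12.95 in untreated and 12.92 in VPA cells, a difference of −0.024 ± 0.11.

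The lists that were higher with VPA held metabolic, repair and stress genes. Sterol and fatty acid synthesis had a mean of 0.14 over 24 genes (adjusted p = 0.033 in camera), DNA repair 0.14 over 25 genes (0.023) and heat shock and oxidative stress 0.12 over 23 genes (0.038). With an estimated correlation the adjusted p was 0.506, 0.597 and 0.606, and 0 members were called when adjusted over each list alone. Sterol genes of smallest p were Sc5d (0.60 ± 0.16, SE), Stard4 (0.49 ± 0.15), Dhcr7 (0.30 ± 0.11) and Lss (0.29 ± 0.11). Among repair genes, 22 were higher and 3 lower, led by the ligase gene Lig4 (0.52 ± 0.14), the checkpoint kinase gene Chek2 (0.45 ± 0.15), Xpc (0.32 ± 0.11) and Brca2 (0.24 ± 0.11). Stress genes of smallest p were Nqo1 at 0.46 ± 0.14, Srxn1 at 0.39 ± 0.12, Gclc at 0.34 ± 0.11 and the heat shock gene Hspb1 at −0.40 ± 0.14. These lists depended on untreated replicate 2: without it their means were 0.095, 0.068 and 0.075 and their adjusted p 0.215, 0.486 and 0.486. Without untreated replicate 1 the repair mean was 0.21. They also missed the threshold without VPA replicate 2 (adjusted p = 0.060, 0.051 and 0.276) and with the dimmer probe sets left out (0.20, 0.168 and 0.152), and the first 2 without VPA replicate 1 (0.078 and 0.062) and after a second quantile normalization (0.132 and 0.091).

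Ribosomal protein genes were lower, with a mean of −0.098 over 25 genes (adjusted p = 0.011 in camera, and adjusted p = 0.506 with an estimated correlation), 19 lower and 6 higher. Their members of smallest p were Rps19 (−0.58 ± 0.14, SE), Rpl14 (−0.35 ± 0.11), Rps14 (−0.32 ± 0.13) and Rpl7 (−0.21 ± 0.12), and 0 were called when adjusted over the list alone. The call was lost after a second quantile normalization (adjusted p = 0.078) and without VPA replicate 1 (0.087). Targets of LIF-STAT3 and MAPK signalling had a mean of −0.068 over 26 genes (adjusted p = 0.057). That mean was −0.033 without VPA replicate 2 and larger in size without VPA replicate 1. Myc, a member of that list, differed by −0.64 ± 0.16. Adjusted over the list alone, Mycn was called lower and Btg2, an antiproliferative gene, higher at 0.66 ± 0.11; among 27 cell cycle inhibitors and p53 targets the same test called Btg2 and Ccng2 (0.59 ± 0.11). Btg2 and Ccng2 were singled out after their values were seen. The inhibitor and p53 list had a mean of 0.072 (adjusted p = 0.406), and of 0.039 without VPA replicate 2.

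The other lists did not shift. Means were 0.093 for 27 cell cycle G2-M genes (adjusted p = 0.094 in camera), with 24 higher and 3 lower, and 0.035 for 28 cell cycle G1-S genes (0.886). They were 0.063 for 28 genes of amino acid and unfolded protein stress (0.443) and 0.091 for 27 genes of fatty acid oxidation and PPAR targets (0.401). Wnt-beta-catenin targets had a mean of −0.075 over 21 genes (0.067) and nuclear-encoded respiratory chain genes 0.031 over 26 genes (0.833). Single arrays moved several of these means. Without untreated replicate 2 the G2-M mean was 0.035 (adjusted p = 0.770), the Wnt mean −0.0086 (0.655) and the fatty acid oxidation mean 0.060, and without untreated replicate 1 the G2-M mean was 0.15 (0.016) and the Wnt mean −0.14 (0.016). The medians of the G1-S and respiratory chain lists were below 0, at −0.0051 and −0.014. In all, 12 of 30 lists passed camera with the preset correlation, 9 lower and 3 higher. With an estimated correlation and with fry's directional test 0 passed, and fry's mixed test called 8. In the simulation for this design, with genes drawn independently, a list moved by −0.2 passed with an estimated correlation in 0 of 20 sets. For lists whose genes vary together the simulation gives no answer. A call lost with an estimated correlation does not by itself show that a list's genes vary together. For 2-cell-like genes that correlation was −0.078, below the preset 0.01, yet the unadjusted p in camera rose from 0.0012 to 0.076. For Polycomb and DNA methylation machinery it was −0.030, and that p rose from 0.0068 to 0.089.

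**Figure D2:**
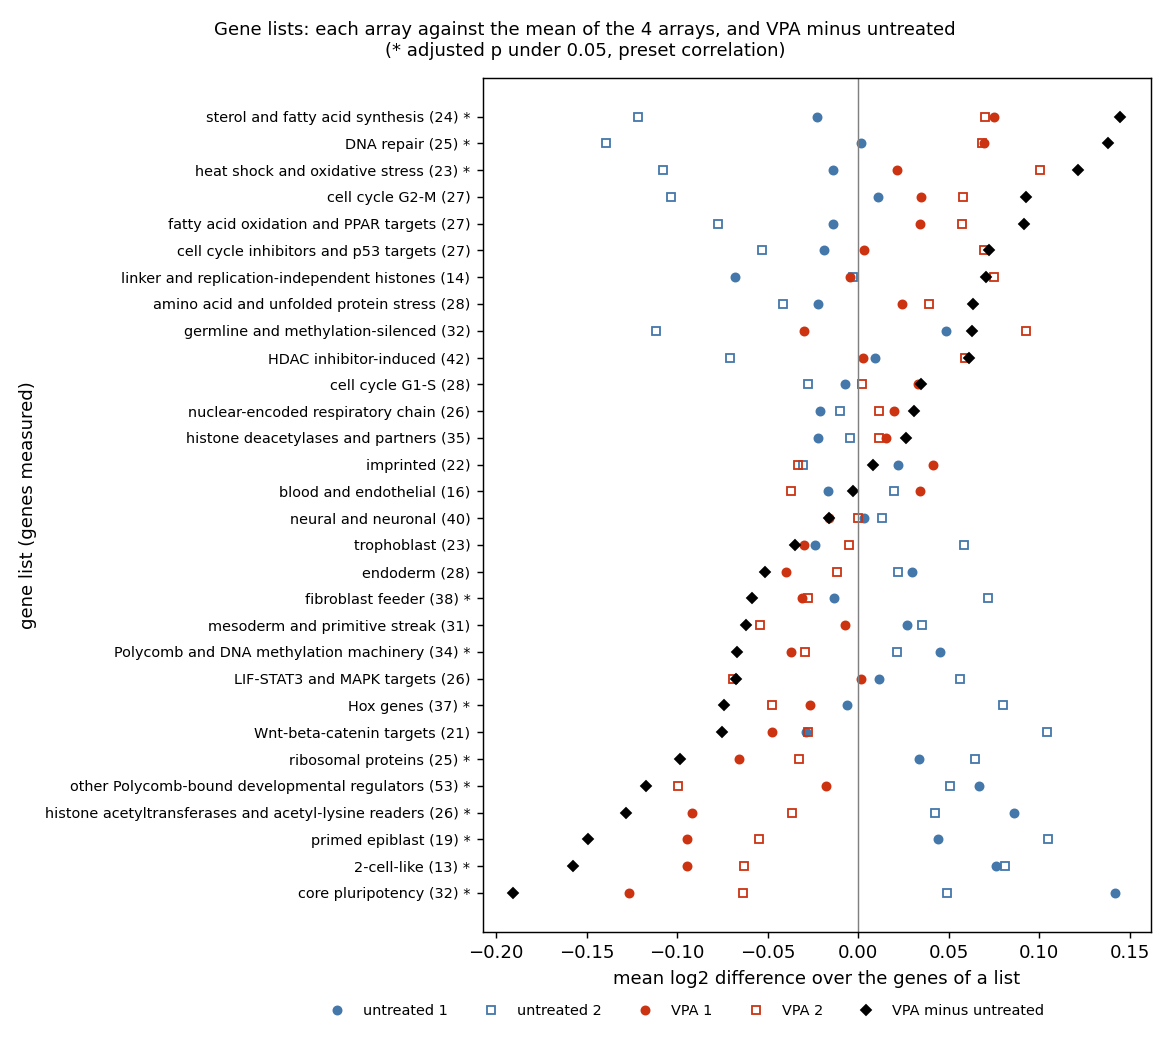
Mean log2 difference over the genes of each of the 30 lists: coloured symbols give each array against the mean of the 4 arrays, black diamonds the VPA mean minus the untreated mean. Core pluripotency has the lowest value (−0.19) and sterol and fatty acid synthesis the highest (0.14); untreated replicate 2 lies furthest to the left in the lists that were higher with VPA.

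A difference by signal level was small and depended on the array. In quartiles of the mean over all arrays, of 8889 probe sets each, the difference was 0.0071 and −0.0066 in the lower quartiles, 0.033 in the third and 0.051 in the highest. Exact two-sided permutation p-values were 1, 0.667, 0.33 and 0.33, the last being the smallest this design allows. In the highest decile the difference was 0.017. Without untreated replicate 1 the quartiles differed by −0.021, −0.019, 0.026 and 0.084, and without untreated replicate 2 by 0.035, 0.0053, 0.040 and 0.019, so the sign turned in the lower 2. After a second quantile normalization the differences in the upper quartiles were −0.0030 and 0.0017. That step makes the sorted values of the arrays alike, so differences by signal level come close to 0 by construction.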

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

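The tests in this part were all chosen after the result was seen. A set of 6617 probe sets without a gene name, whose identifiers come before the lowest identifier that has one, was higher with VPA. These probe sets represent no named gene and are in no gene list, but they entered the fit and the adjustment over all probe sets. Their mean was 4.13 in untreated and 4.20 in VPA cells, a difference of 0.072 on the log2 scale, against 0.019 for the 23410 named probe sets and −0.033 for the other 5529 unnamed ones. At an unadjusted p under 0.05, 653 of them were higher and 315 lower.

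Their signal level is argued against as a reason, since 1000 draws of named probe sets matched on mean signal gave a mean difference of at most 0.012. A single deviating array is also argued against, because the difference was at least 0.060 with each array left out in turn, and so are distributions left unequal by the normalization, because it was 0.056 after a second quantile normalization. What these probe sets measure is not given in the sources used here, so their base composition and probe type may differ from those of named ones and stay untested. An effect of the treatment on the transcripts they detect stays open too.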

How the results depend on the processing

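The alternatives were fixed before the data were examined, except for the fit without the unnamed low-identifier probe sets. That fit, and the counts at an unadjusted p under 0.05 taken under each alternative, were chosen after seeing the data. Under every alternative run, an adjusted p under 0.10 included, 0 probe sets were called. Of the named genes' values under the alternatives, 1164 kept their direction and 14 turned. The count of 1164 includes alternatives that alter only the test or the probe sets tested, where a gene's difference could not turn. They were trend and robust options, a minimum fold, a replicate block and a single probe set per gene. Leaving out the dimmer or the unnamed low-identifier probe sets also left these differences as they were. The count of 1164 is therefore no measure of how stable the directions were. Of the lists' tests 284 kept the test's direction and side of the threshold, 54 lost the call, 7 gained it and 15 turned. The test's direction is that against the other genes and can differ from the sign of the mean. The mean itself took the other sign in 9 cases from 5 lists, and in 6 of these the test's direction was kept. Only 4 arrays and signals near the low end of the scale limit what can be detected, and the cause of a change below was not tested unless stated. Where an array is left out, the lone array of its group is assumed to vary like the other group.

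For probe sets at an unadjusted p under 0.05, the minimum fold of 1.2 in treat, which asks for more than a difference, left 831 (614 higher, 217 lower). Leaving out the dimmer probe sets, so that fewer were tested, left 764 lower. Leaving out the unnamed low-identifier probe sets gave 3365 (1969 higher, 1396 lower). With each array left out the count ran from 1827 (without VPA replicate 2; 2118 without VPA replicate 1) to 4242, those higher from 1181 to 2524 and those lower from 646 to 1718. The count of 990 probe sets at least 1.5-fold apart became 3240 (2147 higher, 1093 lower) at 1.3-fold, 138 (106 and 32) at 2-fold and 604 (429 and 175) without the dimmer probe sets. With each array left out it ran from 1432 to 2393, those higher from 935 to 1520 and those lower from 497 to 873, where a lone array makes overlap rarer by construction. Its highest value was without untreated replicate 1, with 1896 without VPA replicate 1 and 1567 without VPA replicate 2.

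For gene lists, an estimated correlation and fry left 0 shifted, 0 up and 0 down. Lists shifted up numbered 1 after a second quantile normalization and 0 with the dimmer probe sets left out. With each array left out 3 to 13 lists passed, 0 to 4 up and 2 to 9 down: 7 passed without untreated replicate 2, 3 without VPA replicate 1 and 7 without VPA replicate 2. Targets of LIF-STAT3 and MAPK gained the call with the mean of all probe sets of a gene, a second quantile normalization or without the dimmer probe sets, Wnt-beta-catenin targets with the last of these or without untreated replicate 1, mesoderm genes without the dimmer probe sets, and G2-M genes without untreated replicate 1. The feeder list lost it with trend and robust options (adjusted p = 0.054) and the heat shock list with the mean of all probe sets (0.052), where these lists' adjusted p ran up to 0.606 over all alternatives. Under fry the test's direction turned for blood and endothelial genes (mean −0.0030) and imprinted genes (0.0084). With the dimmer probe sets left out, so that the comparison was with brighter genes only, it turned for genes responding to deacetylase inhibitors (0.063), deacetylases and partners (0.027, as against 0.026), G1-S genes (0.035), blood and endothelial genes (0.081) and respiratory chain genes (0.031). With each array left out it turned in at least 1 case for imprinted genes (means from −0.029 to 0.046), germline genes (−0.017 to 0.14), genes responding to deacetylase inhibitors (0.021 to 0.10), G1-S genes (0.019 to 0.050) and blood and endothelial genes (−0.039 to 0.033). After a second quantile normalization the mean itself was below 0 for deacetylases and partners (−0.018) and imprinted genes (−0.024). None of these lists whose direction turned passed the test in the fit as reported.

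Among named genes, Hoxb1 was at −0.0032 after median centring and −0.043 after a second quantile normalization, which also gave −0.015 for Clu and −0.0054 for Gsn. With each array left out the log2 difference ran from −0.044 to 0.049 for Hoxb1, −0.088 to 0.039 for Actb, −0.048 to 0.43 for Hdac11, −0.078 to 0.19 for Clu, −0.013 to 0.15 for Gsn, −0.026 to 0.30 for Txnip and −0.013 to 0.41 for Sox2. The third signal quartile differed by 0.044 as a median and by −0.0030 after a second quantile normalization, and the highest by 0.0017 after it. That normalization brings quartile differences close to 0 by construction.

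Whether samples of the same replicate number were handled together is not stated in the labels. The correlation over probe sets of the replicate difference in untreated with that in VPA cells was −0.097. With a replicate block 0 probe sets were called, 2576 had an unadjusted p under 0.05 (1677 higher, 899 lower), and 12 lists passed.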

Other observations

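The core pluripotency and feeder lists were fixed before the data were examined. The other gene groups, and the tests of explanations in this part, were chosen after the values were seen. Leaving out the genes that prompted a group does not free its other members from that choice. The p-values of these groups are therefore descriptive. Lysosomal genes were higher with VPA: of 28 measured, 27 had a higher mean and 1 a lower one, with a mean difference of 0.26 on the log2 scale (adjusted p = 4.8e-07 over 13 such groups in camera with the preset correlation, and adjusted p = 0.284 with an estimated correlation). Without Lipa and Gla, which prompted the group, the mean was 0.22 (adjusted p = 3.3e-05, and adjusted p = 0.393 with an estimated correlation). Lipa, the acid lipase, led with 0.97 ± 0.11 (SE), followed in order of p by the membrane protein gene Lamp2 at 0.68 ± 0.16, Gla at 0.46 ± 0.13, the channel gene Mcoln1 at 0.42 ± 0.13 and the cathepsin gene Ctsl at 0.45 ± 0.14. Cln3 was at 0.38 ± 0.12, Ctsz at 0.31 ± 0.11 and Scarb2, the single lower member, at −0.22 ± 0.15. The mean was 0.21 after a second quantile normalization and between 0.20 and 0.32 with each array left out. Of 27 autophagy genes, 18 were higher and 9 lower, with a mean of 0.10 (adjusted p = 0.125 in camera). After a second quantile normalization the autophagy mean was 0.041 (adjusted p = 0.405 in camera). Gabarapl1 was at 0.79 ± 0.12, while the transcription factor genes Tfeb and Tfe3, which drive lysosomal genes, were at −0.42 ± 0.15 and −0.30 ± 0.12.

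Large chromatin regulators were lower. Without Setd1b, Brpf3, Asxl1 and Crebbp, which prompted the group, 21 of 27 had a lower mean and 6 a higher one, with a mean difference of −0.16 (adjusted p = 0.00026 with the preset correlation, and adjusted p = 0.305 with an estimated correlation). Arid1a (a chromatin remodelling subunit) was at −0.59 ± 0.14 (SE), Srcap at −0.55 ± 0.12, Setd1a at −0.55 ± 0.17 and Bcor at −0.60 ± 0.18. Bcorl1 and Setd2 went the other way at 0.49 ± 0.16 and 0.38 ± 0.11. With the prompting genes the mean was −0.23 over 31 genes, −0.28 after a second quantile normalization and between −0.28 and −0.17 with each array left out. Ep300, Kat6a, Kat6b and Brpf1 also belong to the list of acetyltransferases and acetyl-lysine readers, so that list and this group are not independent. A signal-dependent trend and gene length were not tested for this group. The Armcx family was prompted by Armcx3, and its 5 other genes did not pass, with a mean of 0.21, 4 higher and 1 lower (adjusted p = 0.074, and adjusted p = 0.393 with an estimated correlation). Among them were Armcx2 at 0.42 ± 0.17, Armcx6 at 0.38 ± 0.11 and Armcx1 at −0.21 ± 0.11. Genes of the Slc35 transporter family, prompted by Slc35f5, did not pass without it either, with a mean of 0.13 over 26 genes (adjusted p = 0.074, and adjusted p = 0.473 with an estimated correlation). With it the mean was 0.16, and with each array left out between 0.083 (without untreated replicate 2) and 0.24 (without untreated replicate 1).

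Other families had smaller values. Means were −0.090 for 23 replication-dependent histones (adjusted p = 0.044 with the preset correlation), −0.059 for 52 small nucleolar RNA genes (0.028), −0.051 for 99 keratins (0.0079) and −0.047 for 484 predicted genes (0.0025). They were −0.025 for 291 microRNA genes (0.045), −0.0042 for 1027 olfactory receptors (0.196), −0.0014 for 167 vomeronasal receptors (0.289) and 0.062 for 347 genes whose symbol is Zfp and a number (0.166). With an estimated correlation the adjusted p of these families lay at or above 0.230. Without untreated replicate 1 the olfactory and vomeronasal receptors passed at −0.031 and −0.038 (adjusted p = 0.031 for each), and without untreated replicate 2 they were at 0.022 and 0.035 (adjusted p = 0.903 and 0.685). The microRNA call was lost after a second quantile normalization (adjusted p = 0.155), without untreated replicate 2 (0.226) and without VPA replicate 2 (0.149). The histone mean ran from −0.20 to 0.024 with each array left out, and its call was lost without untreated replicate 2 (adjusted p = 0.903) and without VPA replicate 2 (0.231). That of small nucleolar RNA genes was lost without untreated replicate 2 (adjusted p = 0.079) and without VPA replicate 1 (0.059).

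The hypothesis for the lower core pluripotency genes is that VPA may reduce their transcripts within 4 h. More feeder RNA in the VPA arrays is argued against by the feeder list, whose mean was −0.059, while the explanation needs it above 0 by at least the size of the fall. A signal-dependent trend is argued against because the list's mean of −0.19 lay at percentile 0 among 10000 random lists matched on mean signal, whose central 95% ran from −0.023 to 0.11. Gene length is argued against because the mean was −0.18 after a linear term for it. Base composition was not tested, and whether the replicates are separate cultures is not stated, so a difference between dishes stays open.

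A second hypothesis is that VPA may raise lysosomal genes together. Their mean lay at percentile 100 among 10000 matched random lists, which argues against a signal-dependent trend, and at 99.99 without Lipa and Gla, the genes that prompted the group. After a linear term for gene length it was 0.26, outside the central 95% of such lists (−0.013 to 0.15). The group was among 13 chosen after the values were seen, so its place among random lists is no evidence for the hypothesis. That place bears only on signal level and gene length as reasons. Differences between dishes, such as medium or density, stay open here too.

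The 4 arrays can be split 2 against 2 in 3 ways, too few for a share under 0.05. Of these, 1 gave as many probe sets at an unadjusted p under 0.05 as the real split, namely itself with 3269, and the highest other gave 1515. Probe sets at least 1.5-fold apart without overlap numbered 990 in the real split and 562 and 644 in the others. In camera with the preset correlation 12 lists passed in the real split, and 0 and 1 in the others. The other splits mix treated and untreated arrays, so a treatment difference widens the spread within their groups. Their counts are therefore no measure of what chance alone gives.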
